A study of Homo sapiens with 20 samples.

How the data were processed

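RNA levels were measured in 20 libraries from 5 established human cell lines. Kasumi-1, NOMO-1 and THP-1 are lines from acute myeloid leukemia (AML), and iHUVEC and TIME are endothelial lines, the cell type that lines blood vessels. Each line gave 1 untreated library and 1 library each after interferon gamma (IFNg), tumor necrosis factor alpha (TNFa) and both together (IFNg+TNFa), at 10 ng/ml of each cytokine for 24 h. Each group of AML libraries therefore held 3 libraries and each group of endothelial libraries 2, with the line as the replicate. No library was repeated within a line, so the errors and p-values of single genes and transcripts below start from the spread between lines. Moderation by limma draws the spread of each gene or transcript toward that of the others, so an error is not that gene's spread alone. The p-values that camera gave for lists of genes at a preset correlation rest mainly on the spread between genes, and do not measure replication over lines.

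Per the labels' protocols, RNA was purified with a QIAGEN kit, made into libraries by a standard Illumina procedure and sequenced on an Illumina NovaSeq. Per the submitters' processing notes, the tools were Salmon 1.2.0 and DESeq2 1.28.1 and the genome build was GRCh38 p13, with no roles stated. The annotation release is not given in the sources used here. The authors deposited TPM values, the usual length-corrected unit of transcript abundance, in a table of 35168 genes and a table of 170068 transcripts. TPM values are read shares corrected for transcript length and keep no total, so the sequencing depth of each library is unknown and no counting interval was given. The columns named x2 were read as the libraries with both cytokines, the only treatment of each line left without a column. Column totals lay between 947940 and 995175 TPM, so a part of the TPM of each library lay outside the listed genes. The column totals of the gene and transcript tables differed by at most 2.33e-10 TPM.

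Gene symbols were taken for 35051 gene IDs from a table of gene names and for 110 from GENCODE v29, and 7 had none. Coordinates are from GENCODE v29 on GRCh38, whose patch level may differ from that of the authors. Genes at 0 in all 20 libraries numbered 10912. Several HLA genes were listed near 0 in lines with high levels of their neighbours, so values of genes in the MHC window of chromosome 6 (28 to 34 Mb) depend on how reads were assigned there.

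Values were analysed as log2(TPM + 1) with limma 3.58.1 in R 4.3.3, using moderated tests with a trend on mean expression, and tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. A log2 change on this scale understates the ratio of weakly expressed genes. Genes with a TPM of at least 1 in at least 2 of the libraries of a fit were tested, p-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Treatments were compared with untreated cells in 1 fit of all 20 libraries with a term for the cell line and for the treatment within each cell type, which left 9 residual degrees of freedom and tested 15043 genes. The same fit gave the difference between the responses of both cell types and the departure of the combined treatment from the sum of the single treatments. AML and endothelial lines were compared directly within the 5 untreated libraries and within the 5 libraries with both cytokines. These fits left 3 residual degrees of freedom, to which moderation added 4.5 for untreated libraries and 28.9 for those with both cytokines. Errors of single genes in the direct comparison after both cytokines therefore come mostly from the trend over all genes. All lines shared 1 estimate of spread per gene in the treatment fit. A gene near 0 in every line of one cell type adds almost no spread there, so its error in the other cell type is understated.

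The line term was chosen from the labels. Deviations of the log values from the group means correlated between 0.65 and 0.90 for the 30 pairs of libraries from 1 line. No pair of libraries was identical. The share of each gene's TPM held by each of its transcripts was tested with limma for the combined treatment over all 5 lines, in genes with a mean TPM of at least 5, at least 1 TPM in every library and transcripts with a mean share from 10 to 90%.

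The 23 lists of genes, fixed with the designs and the rule for named genes before the data were examined, were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over all 294 tests of a list in a comparison. Lists with at least 5 tested members were used. They held genes of the IFNg response, MHC class I and class II presentation, type I interferon stimulation, NF-kB targets, chemokines, cytokines, leukocyte adhesion, T-cell ligands, AML surface antigens, endothelial markers and surface antigens, hematopoietic, fibroblast and mural, epithelial and lymphoid markers, cell cycle, cell death, cytokine receptors and signalling, myeloid differentiation, mitochondrial mRNAs, features of AML lines, and vasoregulation and coagulation. The list members LTA and ADAMTS13 were not used here. At the preset correlation 136 of the 294 tests passed, and 11 passed with a correlation estimated from the data. Those 11 were the IFNg core list in both cell types after IFNg, and MHC class I presentation in endothelial lines after IFNg. They also included chemokines and cytokines in endothelial lines after TNFa and after both cytokines, and endothelial markers in endothelial lines after TNFa, in the difference between the responses to both cytokines and in both direct comparisons of the cell types. The self-contained test fry, which asks whether a list's genes move on balance in 1 direction, passed in 53.

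After both cytokines the small lists of other cell types gave these results. Among fibroblast and mural markers 1 of 9 tested members rose and 0 fell in AML lines (adjusted p = 0.059), and 1 rose and 1 fell in endothelial lines (adjusted p = 0.172). Among epithelial markers 1 of 6 rose and 0 fell in AML lines (adjusted p = 0.983), and 1 rose and 2 fell in endothelial lines (adjusted p = 0.404). Among lymphoid markers 1 of 6 rose and 1 fell in AML lines (adjusted p = 0.940), and 0 rose or fell in endothelial lines (adjusted p = 0.704). Among features of AML lines 3 of 9 fell in AML lines (adjusted p = 0.356). Of 13 mitochondrial mRNAs, 2 fell in AML lines and 0 adjusted over the list alone (adjusted p = 0.416), and none of the 13 passed in endothelial lines, where the list was lower (adjusted p = 0.048, and 0.765 with an estimated correlation). Cytokine receptor and signalling genes rose in 8 of 19 cases in AML lines (adjusted p = 1.1e-10, and 0.201 with an estimated correlation) and in 7 of 19 in endothelial lines (adjusted p = 5.2e-12, and 0.176 with an estimated correlation). Of 22 myeloid differentiation genes 6 rose and 5 fell in AML lines (adjusted p = 0.069).

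The rule for named genes took the 8 largest rises and 8 largest falls of each treatment comparison and each direct comparison among called genes that moved the same way in every line. For response differences, departures from additivity and transcript shares it took the 5 largest in each direction. It also took up to 4 called members of each list, or up to 2 with the largest change where none was called, and a panel of 20 surface, signalling and cytokine response genes. Genes with clone or pseudogene names were left out, and some genes that the rule named are not reported here. ANKRD26P1, CDKN1A, IFNB1, IFNL1 and HLA-DRB1 were outside this rule and were chosen after their values were seen. GFI1, GHRL, RUNX1T1, EPCAM and CD74 were named by the rule in some comparisons, and HLA-DRA was on the panel, but their TPM values in single libraries were chosen after they were seen.

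The tests were run on simulated data with the measured spread of each gene and a set of genes changed by known amounts. Treatment comparisons used the measured mean of each line. The changed genes were drawn from those well above 0, so the recovered shares do not apply to weakly expressed genes. The simulated noise of a gene had the same size in every library, unlike that of genes near 0 in AML or in endothelial lines. For both cytokines in AML lines, 40.3%, 85.1% and 95.5% of genes changed by 1, 2 and 4 log2 were recovered among 14695 tested. For TNFa in AML lines the shares were 26.9%, 80.6% and 98.5% among 14693. For both cytokines in endothelial lines they were 11.9%, 79.1% and 98.5% among 14709, and for the response difference 9.0%, 37.3% and 81.8% among 14684. For AML against endothelial lines, simulated with the same mean for every line, 0 of the genes changed by 1, 2 or 4 log2 were recovered among 13068. A further simulation with larger changes, added because the first recovered none, recovered 19.4%, 62.7% and 78.8% of genes changed by 4, 6 and 8 log2 among 13093. Direct comparisons of the cell types therefore had little power for differences of 4 log2 or less when few genes differ.

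The alternatives tried were a pseudocount of 0.1, no filter on low values, a filter at 5 TPM, median-of-ratios scaling of the TPM columns, no trend in the variance, no line term, only the libraries of 1 cell type, and each line left out in turn. For the direct comparisons all libraries were also fitted with the line as a random term. For transcript shares a mean gene TPM of at least 20 and an arcsine square root scale were tried as well. After the data were seen, a further alternative removed mitochondrial genes, because they held 72.4 to 81.6% of TPM in the 4 NOMO-1 libraries and 11.5 to 24.3% in the others.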

Results

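Transcript levels were measured by RNA sequencing in 3 AML lines and 2 endothelial lines, untreated and after 24 h with IFNg, TNFa or both, in 20 libraries. The comparisons bear on the choice of surface antigens for engineered T cells, for which a target should be present on leukemia cells and absent from endothelium, also during inflammation. Surface protein was not analysed here, so the values below are of transcripts only. The deposited values were TPM, so depth is unknown, and between 7510 and 12353 genes reached 1 TPM in a library. Mitochondrial genes held 72.4 to 81.6% of TPM in the 4 NOMO-1 libraries and 11.5 to 24.3% in the others, which lowers every other gene of NOMO-1 on the TPM scale. Changes are log2 differences on log2(TPM + 1) ± the moderated standard error, with 3 AML lines and 2 endothelial lines. Adjusted p-values are from limma.

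Untreated AML and endothelial lines were compared first, for the antigens and markers that part them. The neutrophil granule protease genes ELANE (9.38 ± 1.39, adjusted p = 0.008), PRTN3 (8.98 ± 1.30, adjusted p = 0.007) and CTSG (8.65 ± 1.39, adjusted p = 0.010) were higher in AML lines, as was SPI1, which encodes a myeloid transcription factor (7.21 ± 0.82). The matrix gene EFEMP1 was lower in AML lines (-10.61 ± 0.69, adjusted p = 0.002), as were the collagenase MMP1 (-10.25 ± 0.68) and the adhesion gene MCAM (-9.72 ± 0.69). CD33, a myeloid antigen used as an AML target, had a mean TPM of 34.6 ± 16.6 (SD) in AML lines and 0.0275 ± 0.0389 in endothelial lines (4.98 ± 0.77, adjusted p = 0.009). CD93 (chromosome 20, 23079349 to 23086340, minus strand, GRCh38) had 2.84 ± 1.78 TPM in AML lines and 233 ± 106 in endothelial lines (-5.98 ± 0.81, adjusted p = 0.006).

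Of 34 tested endothelial markers, 30 were lower in AML lines and 34 when adjusted over the list alone, among them the cadherin CDH5 (-8.66 ± 0.68), the receptor TIE1 (-8.04 ± 0.70) and PECAM1 (-5.87 ± 0.94), with a camera adjusted p of 6.4e-26. Endothelial surface antigens were lower in 43 of 54 cases, and in 49 adjusted over the list alone, including ICAM2 (-6.46 ± 0.85). The list had a camera adjusted p of 2.8e-28, and 0.097 with an estimated correlation. Vasoregulation and coagulation genes were lower in 9 of 13 cases, also adjusted over the list alone, including the vasoconstrictor EDN1 (-7.35 ± 0.68) and TFPI2 (-6.82 ± 0.73). For these genes the camera adjusted p was 2.8e-07, and 0.124 with an estimated correlation. Hematopoietic and myeloid markers were higher in AML lines in 16 of 33 cases and in 23 adjusted over the list alone, with the integrin chain ITGB2 (6.16 ± 0.79) and MYB (5.72 ± 1.06) among those that were higher. The camera adjusted p of that list was 1.5e-33, and 0.135 with an estimated correlation. Of 23 AML surface antigens, 6 were higher in AML lines (10 without NOMO-1) and 1 lower, and 12 and 1 adjusted over the list alone, with the Fc receptor FCGR1A (5.48 ± 1.04) and SPN (5.12 ± 1.04) higher and CD93 lower. Tested with camera, the list had an adjusted p of 3.2e-12, and 0.141 with an estimated correlation. CLEC12A (2.21 ± 0.65, adjusted p = 0.088) and IL3RA (0.89 ± 0.61, adjusted p = 0.424) did not pass the test, and CD274, the ligand of PD-1, was lower in AML lines (-3.52 ± 0.56, adjusted p = 0.010).

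Of 12948 genes tested without treatment, 1099 differed, 132 higher and 967 lower in AML lines. The count was 480 without a filter on low values, 1711 without Kasumi-1, 460 without THP-1, 126 without iHUVEC and 105 without TIME. Under median-of-ratios scaling 177 were higher and 687 lower, with mitochondrial genes removed 184 and 812, and without NOMO-1 264 and 1113. The median over all tested genes was -0.88 log2 and moved to -0.08 under median-of-ratios scaling, to -0.33 with mitochondrial genes removed and to -0.35 without NOMO-1. Of the 26 named and called genes 11 kept their call without any 1 line, and those that did not include EFEMP1, MMP1, MCAM, CD33, CD93, CDH5 and CD274.

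**Figure D1:**
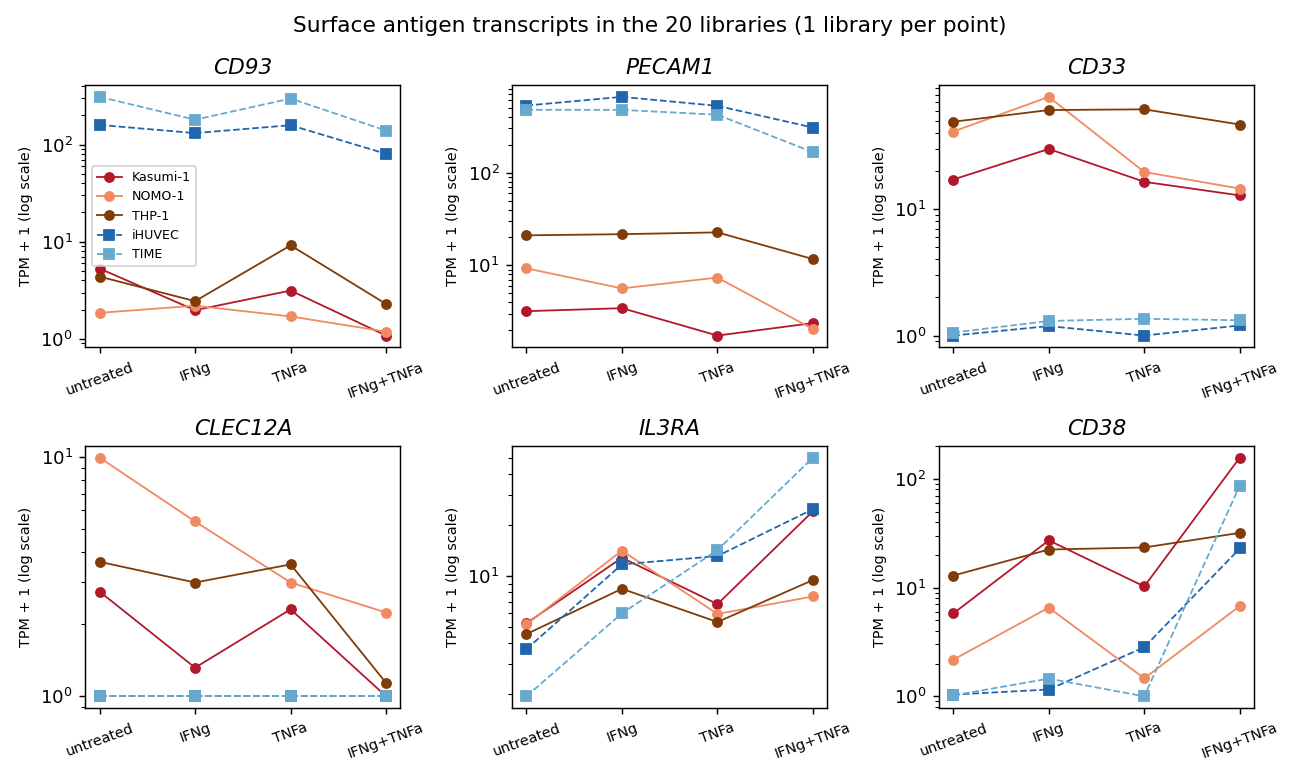
TPM + 1 of 6 surface antigen genes on a log scale in each of the 20 libraries, by treatment. Circles and solid lines are AML lines and squares and dashed lines are endothelial lines, with CD93 between 79.2 and 308 TPM in endothelial libraries and IL3RA at 49.0 TPM in TIME after IFNg+TNFa.

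After both cytokines the cell types were compared again, since inflammation accompanies engineered T cells. NCF1, a subunit of the phagocyte oxidase, was higher in AML lines (9.55 ± 1.33, adjusted p = 4.0e-05), as were SPI1 (8.23 ± 1.32), TYROBP (7.58 ± 1.34) and the interleukin 1 receptor antagonist IL1RN (7.04 ± 1.35). The matrix gene FN1 (-9.45 ± 1.31) and the membrane chemokine CX3CL1 (-9.47 ± 1.3, adjusted p = 3.5e-05) were lower in AML lines. CD33 stayed higher in AML lines (4.03 ± 1.17, adjusted p = 0.030) and CD93 lower (-6.20 ± 1.2, adjusted p = 0.001). IL3RA, the receptor chain CD123, did not pass (-1.55 ± 1.3, adjusted p = 0.694), with 12.7 ± 9.04 TPM in AML lines and 36.4 ± 17.8 in endothelial lines, and CD274 did not pass either (-2.10 ± 1.40, adjusted p = 0.557).

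Endothelial markers were lower in AML lines after both cytokines in 31 of 32 cases (camera adjusted p = 1.1e-37), and in 32 adjusted over the list alone, including CDH5 (-8.05 ± 1.22) and PECAM1 (-5.86 ± 1.31). Endothelial surface antigens were lower in 40 of 53 cases and 46 adjusted over the list alone, SELE among them (-3.60 ± 0.75). As a set they had a camera adjusted p of 1.7e-35, and 0.149 with an estimated correlation. Hematopoietic markers were higher in 18 of 32 cases and 27 adjusted over the list alone, including PTPRC (5.46 ± 1.48), with a camera adjusted p of 2.4e-42, and 0.151 with an estimated correlation. AML surface antigens were higher in 7 of 29 cases (11 without NOMO-1) and lower in 1, and 16 and 2 adjusted over the list alone, with a camera adjusted p of 7.7e-14, and 0.369 with an estimated correlation. Chemokines were lower in AML lines in 6 of 21 cases, including CXCL2 (-5.65 ± 1.27), and higher in 1, CCL4 (6.64 ± 1.30), and 8 and 2 adjusted over the list alone. By camera, the adjusted p of the list was 0.003, and 0.545 with an estimated correlation. Vasoregulation genes were lower in 9 of 15 cases and 11 adjusted over the list alone, including TFPI2 (-9.27 ± 1.25) and the cyclooxygenase PTGS2 (-6.33 ± 1.29), with a camera adjusted p of 1.0e-11, and 0.152 with an estimated correlation.

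Of 12644 genes tested, 860 differed, 127 higher and 733 lower in AML lines. The count was 0 without iHUVEC, 1 without TIME, 1687 without Kasumi-1, 0 without a filter on low values and 368 without the variance trend, and each of the 25 named and called genes lost its call in at least 1 fit without a line. The count at an unadjusted p under 0.05 was 2066 with all lines, and without iHUVEC or TIME a single endothelial library was compared with the AML lines. Under median-of-ratios scaling 166 were higher and 548 lower, with mitochondrial genes removed 183 and 582, and without NOMO-1 164 and 463. The median over all tested genes was -0.83 log2 and moved to -0.03, -0.18 and -0.14 in these fits.

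IFNg alone was compared with untreated cells, first in the AML lines. The guanylate binding protein genes GBP1 (8.16 ± 0.84, adjusted p = 5.7e-04), GBP5 (6.97 ± 0.77), GBP2 (6.66 ± 0.66) and GBP4 (6.53 ± 0.68) rose, all of them targets of interferon. The transcription factor IRF1 (4.27 ± 0.31, adjusted p = 6.6e-05) and the feedback inhibitor SOCS1 (5.06 ± 0.60) rose as well. CXCL10, a chemokine for T cells, rose by 7.21 ± 1.43 (adjusted p = 0.043) and CD274 by 2.92 ± 0.59 (adjusted p = 0.047). IFT122, a gene of intraflagellar transport, fell by 0.99 ± 0.20 (adjusted p = 0.049).

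Of 42 genes of the IFNg core list, 29 rose in AML lines and 39 adjusted over the list alone (camera adjusted p = 2.2e-73), including ETV7 (5.57 ± 0.52) and SECTM1 (5.79 ± 1.11). MHC class I presentation genes rose in 7 of 21 cases and in 14 adjusted over the list alone, among them the peptide transporter TAP1 (5.16 ± 0.61), PSMB9 (3.29 ± 0.67) and HLA-E (2.60 ± 0.38), which lie in the MHC window, and B2M (2.51 ± 0.29), which does not. The camera adjusted p of that list was 6.6e-22, and 0.068 with an estimated correlation. In MHC class II presentation 1 of 15 genes rose, CD74 (3.05 ± 0.54), and 5 adjusted over the list alone, with a camera adjusted p of 6.0e-09, and 0.151 with an estimated correlation. Type I interferon-stimulated genes rose in 7 of 34 cases, including EPSTI1 (5.04 ± 0.69), ISG20 (4.98 ± 0.94) and IFITM1 (5.81 ± 1.05), and 30 adjusted over the list alone, but in 2 without NOMO-1. Their median change was 5.33 in Kasumi-1, 1.69 in NOMO-1 and 1.94 in THP-1. The list had a camera adjusted p of 9.5e-34, and 0.151 with an estimated correlation. Of 35 AML surface antigens 1 rose, FCGR1A (3.25 ± 0.52), also adjusted over the list alone, and IL3RA (1.21 ± 0.39, adjusted p = 0.296) and CD93 (-0.67 ± 0.37, adjusted p = 0.645) did not pass.

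Of 15043 genes, 97 changed with IFNg in AML lines, 96 higher and 1 lower. The count was 7 with no replicate block, 187 under median-of-ratios scaling, 153 with mitochondrial genes removed, 49 without a filter, 42 without Kasumi-1, 25 without THP-1, 29 without iHUVEC and 29 without TIME. CXCL10, IFITM1, SECTM1, IFT122 and ISG20 lost their calls without NOMO-1, and PSMB9, HLA-E, CD74, EPSTI1, CXCL9, ICAM1, CD274 and FCGR1A without another line. Under median-of-ratios scaling 174 genes were higher and 13 lower, and with mitochondrial genes removed 142 and 11. IFT122 also lost its call under scaling.

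In endothelial lines IFNg raised IDO1, the enzyme that degrades tryptophan, by 9.24 ± 1.11 (adjusted p = 0.003), from 0.183 ± 0.0217 to 742 ± 274 TPM (SD). The lysosomal thiol reductase IFI30 (8.09 ± 1.3), the invariant chain gene CD74 (7.63 ± 0.66, adjusted p = 1.8e-04), GBP4 (7.59 ± 0.83) and GBP5 (7.24 ± 0.95) also rose. ADTRP, a regulator of tissue factor pathway inhibitor, fell by 2.02 ± 0.33 (adjusted p = 0.017), GPR4, a proton-sensing receptor, by 1.45 ± 0.27 (adjusted p = 0.036), and HHIP, an inhibitor of hedgehog signals, by 1.12 ± 0.19 (adjusted p = 0.021).

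Of the IFNg core list, 15 of 42 genes rose in endothelial lines and 37 adjusted over the list alone (camera adjusted p = 5.6e-86), including IRF1 (4.61 ± 0.38). MHC class I presentation genes rose in 8 of 21 cases and in 15 adjusted over the list alone (camera adjusted p = 2.2e-40), including TAP1 (4.76 ± 0.75), TAP2 (3.13 ± 0.38) and PSMB9 (4.22 ± 0.82), all in the MHC window. In MHC class II presentation 4 of 15 rose, also adjusted over the list alone, including CIITA, the class II transactivator (4.92 ± 0.87), and the protease CTSS (4.47 ± 0.68). For these genes the camera adjusted p was 1.2e-09, and 0.141 with an estimated correlation. T-cell ligands rose in 3 of 24 cases and 5 adjusted over the list alone, IDO1 being on that list with LGALS9 (5.95 ± 0.70) and the PD-1 ligand PDCD1LG2 (2.34 ± 0.30). Tested with camera, the list had an adjusted p of 7.3e-08, and 0.244 with an estimated correlation. CXCL9 (5.17 ± 1.05, adjusted p = 0.062), CXCL10 (4.75 ± 1.76, adjusted p = 0.648) and ICAM1 (2.41 ± 0.52, adjusted p = 0.083) did not pass.

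With IFNg 64 genes changed in endothelial lines, 52 higher and 12 lower. The count was 11 with no replicate block, 105 without a filter, 36 with endothelial libraries alone, 22 without THP-1 and 117 without iHUVEC, and under median-of-ratios scaling 57 were higher and 2 lower. Without any 1 line 4 of the 20 named and called genes kept their call, IDO1, CD74, TAP2 and IRF1, and GPR4 also lost its call under scaling and ADTRP and GPR4 without NOMO-1. Of the genes that rose, 29 rose in both cell types. Calls in both cell types came from 1 fit with 1 spread per gene over all 20 libraries, so they are not independent.

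TNFa alone raised genes of the NF-kB pathway in AML lines. The cytokine gene IL32 rose by 4.64 ± 0.67 (adjusted p = 0.015), TNFAIP3, an inhibitor of NF-kB signalling, by 4.01 ± 0.47 (adjusted p = 0.006), and the adhesion gene ICAM1 by 3.79 ± 0.42 (adjusted p = 0.005). FTH1, the ferritin heavy chain, rose by 3.21 ± 0.30 (adjusted p = 0.001), the sugar transporter SLC2A6 by 4.21 ± 0.53 (adjusted p = 0.007), and GHRL, which encodes ghrelin, by 3.15 ± 0.43 (adjusted p = 0.011).

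Of 29 tested NF-kB genes, 6 rose with TNFa in AML lines (10 without NOMO-1) and 14 adjusted over the list alone, including NFKBIA (3.43 ± 0.48) and RELB (2.95 ± 0.37). As a set they had a camera adjusted p of 1.6e-28, and 0.141 with an estimated correlation. Of 23 chemokines 0 passed over all genes, where 5 did adjusted over the list alone, and CCL2 (3.98 ± 0.72, adjusted p = 0.066) and CXCL8 (3.55 ± 0.70, adjusted p = 0.096) changed most among the named ones. By camera, the adjusted p of the list was 2.0e-07, and 0.151 with an estimated correlation.

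With TNFa 13 genes changed in AML lines, all higher, and the limma count of lower genes was 0. In either direction 1044 of 15043 genes had an unadjusted p under 0.05, where a share of 0.05 arises without any change. The count of called genes was 0 with no replicate block, 55 under scaling, 57 with mitochondrial genes removed, 32 with a pseudocount of 0.1, 22 at 5 TPM and 3 with AML libraries alone. It was 33 without Kasumi-1, 43 without NOMO-1, 5 without THP-1 and 0 without iHUVEC or TIME, so each named gene lost its call in at least 1 of these fits.

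In endothelial lines TNFa raised the monocyte chemokine CCL2 by 8.70 ± 0.88 (adjusted p = 3.0e-04), the protease MMP10 by 5.85 ± 0.42 (adjusted p = 1.8e-05), ICAM1 by 5.80 ± 0.52 (adjusted p = 1.0e-04) and the adhesion gene SELE, which encodes E-selectin, by 3.90 ± 0.42 (adjusted p = 4.7e-04). CSF2, the gene of GM-CSF, rose by 4.76 ± 0.27 (adjusted p = 1.6e-06), to 29.2 ± 18.8 TPM (SD) from 0 in the untreated libraries. LYVE1, a hyaluronan receptor, fell by 2.79 ± 0.23 (adjusted p = 4.1e-05), the sialomucin EMCN by 2.45 ± 0.33 (adjusted p = 0.002), and NOS3, the endothelial nitric oxide synthase, by 1.63 ± 0.32 (adjusted p = 0.031). IL3RA rose by 2.35 ± 0.47 (adjusted p = 0.034), a call lost without NOMO-1.

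Chemokines rose with TNFa in 9 of 23 cases in endothelial lines and in 12 adjusted over the list alone (camera adjusted p = 2.9e-22), including CXCL8 (5.42 ± 0.86), CCL20 (5.18 ± 0.56) and CX3CL1 (5.09 ± 0.63). Cytokines rose in 6 of 22 cases and in 10 adjusted over the list alone (camera adjusted p = 3.4e-20), including IL32 (4.88 ± 0.82) and IL1A (2.69 ± 0.50). NF-kB genes rose in 10 of 29 cases and in 21 adjusted over the list alone, including TRAF1 (5.41 ± 1.09), EBI3 (5.37 ± 1.03), BIRC3 (5.34 ± 0.68) and TNFAIP3 (3.96 ± 0.58). The list had a camera adjusted p of 1.5e-36, and 0.095 with an estimated correlation. Endothelial markers fell in 4 of 35 cases and in 8 adjusted over the list alone, where 3 rose (camera adjusted p = 1.5e-04), with SOX18, a vascular transcription factor (-2.45 ± 0.38), among those that fell. Type I interferon-stimulated genes rose in 1 of 34 cases, EPSTI1 (4.46 ± 0.84), and in 29 adjusted over the list alone, with a camera adjusted p of 2.9e-33, and 0.151 with an estimated correlation. Their median change was 4.82 in the iHUVEC library and 1.96 in that of TIME. VCAM1 did not pass (4.75 ± 1.21, adjusted p = 0.109).

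With TNFa 154 genes changed in endothelial lines, 118 higher and 36 lower. The count was 16 with no replicate block, 81 with a pseudocount of 0.1 and 55 without THP-1, and 8 of the 26 named and called genes kept their call without any 1 line, MMP10, ICAM1, SELE, CSF2, LYVE1, EMCN and CX3CL1 among them. With iHUVEC or TIME left out, the spread came from AML lines alone. MMP10, SELE, CSF2, LYVE1, EMCN and CX3CL1 were near 0 in AML lines, so their kept calls say little about the spread between endothelial lines. Of the genes that rose, 6 rose in both cell types.

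**Figure D2:**
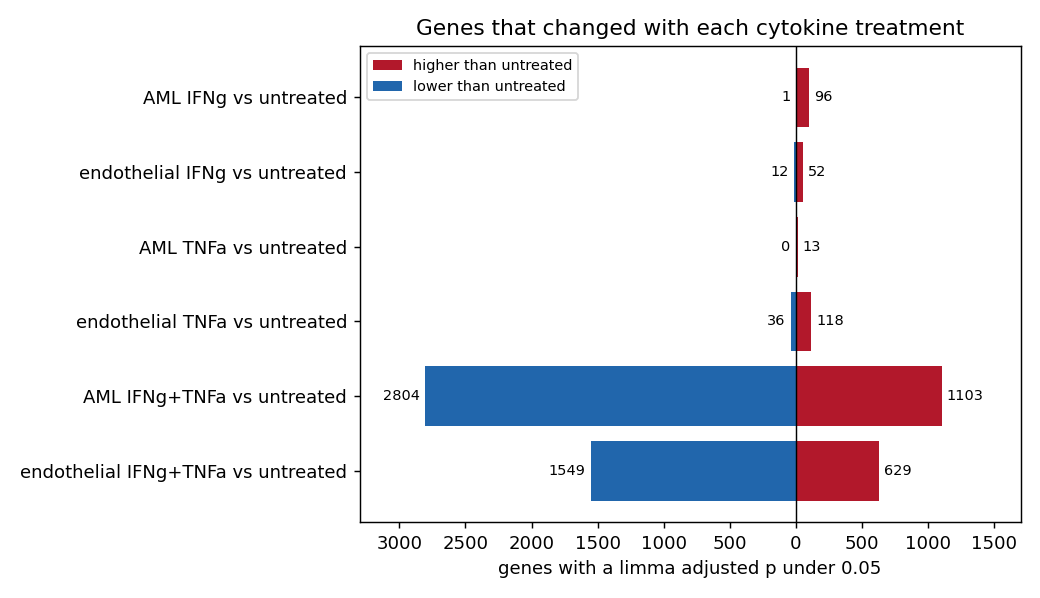
Number of genes with a limma adjusted p under 0.05 in each treatment comparison of 15043 tested genes, with genes higher than untreated to the right and genes lower to the left. The bars run from 13 higher and 0 lower genes for TNFa in AML lines to 1103 higher and 2804 lower genes for IFNg+TNFa in AML lines.

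Both cytokines together gave the largest counts in both cell types. In AML lines CXCL10 rose by 11.63 ± 1.43 (adjusted p = 3.6e-04), CXCL9 by 9.95 ± 0.86 (adjusted p = 6.8e-05) and IDO1 by 7.49 ± 0.91 (adjusted p = 3.3e-04). The granule protease genes CTSG (-6.35 ± 0.78, adjusted p = 3.6e-04), PRTN3 (-5.15 ± 0.69, adjusted p = 5.7e-04) and ELANE (-4.94 ± 0.82, adjusted p = 0.002) fell, as did MPO, the myeloperoxidase gene (-3.73 ± 0.88), and the progenitor transcription factor MYB (-3.13 ± 0.50). EGR2, a transcription factor of macrophage differentiation, rose by 2.91 ± 0.30 (adjusted p = 1.3e-04).

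All but 3 of the 42 IFNg core genes rose in AML lines after both cytokines, 39 in all and 39 adjusted over the list alone, including GBP1 (9.50 ± 0.84). For these genes the camera adjusted p was 2.2e-40, and 0.095 with an estimated correlation. Type I interferon-stimulated genes rose in 31 of 34 cases and 33 adjusted over the list alone, including ISG20 (7.46 ± 0.94) and IFI27 (7.46 ± 1.35), with a camera adjusted p of 8.1e-25, and 0.204 with an estimated correlation. NF-kB genes rose in 23 of 29 cases and 24 adjusted over the list alone, including SOD2 (5.49 ± 0.48) and BCL2A1 (5.20 ± 0.70), with a camera adjusted p of 9.7e-24, and 0.151 with an estimated correlation. MHC class II presentation genes rose in 8 of 15 cases and 11 adjusted over the list alone, including IFI30 (5.57 ± 1.05) and CIITA (2.63 ± 0.71), with a camera adjusted p of 4.5e-08, and 0.151 with an estimated correlation. Chemokines rose in 11 of 23 cases and 12 adjusted over the list alone, including CCL2 (7.74 ± 0.72), with a camera adjusted p of 2.0e-10, and 0.095 with an estimated correlation. Cell death genes rose in 12 of 24 cases, including CASP1 (3.13 ± 0.76) and FAS (2.88 ± 0.73), and adjusted over the list alone 16 rose and 1 fell. Tested with camera, the list had an adjusted p of 6.0e-10, and 0.317 with an estimated correlation.

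All 30 cell cycle genes fell in AML lines, also adjusted over the list alone, including the replication genes CDC45 (-2.89 ± 0.57) and MCM4 (-2.84 ± 0.54) and the topoisomerase TOP2A (-2.62 ± 0.42). As a set they had a camera adjusted p of 2.0e-11, and 0.428 with an estimated correlation, and 20 of the 30 fell without NOMO-1, whose mitochondrial share was 75.5% untreated and 81.6% with both cytokines. Of 35 AML surface antigens 10 rose and 7 fell, and 11 and 8 adjusted over the list alone, with a camera adjusted p of 0.028, and 0.608 with an estimated correlation. The sialoadhesin gene SIGLEC1 (4.08 ± 0.68), CD38 (2.57 ± 0.68) and IL3RA (1.27 ± 0.39, adjusted p = 0.030) were among those that rose. The stem cell factor receptor KIT (-2.09 ± 0.60), CLEC12A (-1.76 ± 0.29, adjusted p = 0.002) and CD93 (-1.29 ± 0.37, adjusted p = 0.024) were among those that fell. T-cell ligands rose in 10 of 24 cases, including CD40 (5.37 ± 0.64) and CD274 (4.52 ± 0.59), and adjusted over the list alone 14 rose and 1 fell. By camera, the adjusted p of the list was 1.4e-09, and 0.191 with an estimated correlation.

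With both cytokines 3907 genes changed in AML lines, 1103 higher and 2804 lower. The count was 66 with no replicate block, 2474 with AML libraries alone, 2078 without iHUVEC and 2052 without TIME, and 39 of the 47 named and called genes kept their call without any 1 line. CD38, IL3RA, KIT and CD93 lost theirs without Kasumi-1, and CIITA, FAS, MPO and VCAM1 lost theirs without at least 1 line. Under median-of-ratios scaling 2307 were higher and 2187 lower, without NOMO-1 1554 were higher and 1691 lower, and with mitochondrial genes removed 1732 were higher and 2965 lower. The excess of lower genes was therefore kept with mitochondrial genes removed, small without NOMO-1 and absent under median-of-ratios scaling. In single lines, genes changed at least 2-fold numbered 594 higher and 3846 lower in NOMO-1, 2673 and 2557 in Kasumi-1, and 1192 and 1341 in THP-1.

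**Figure D3:**
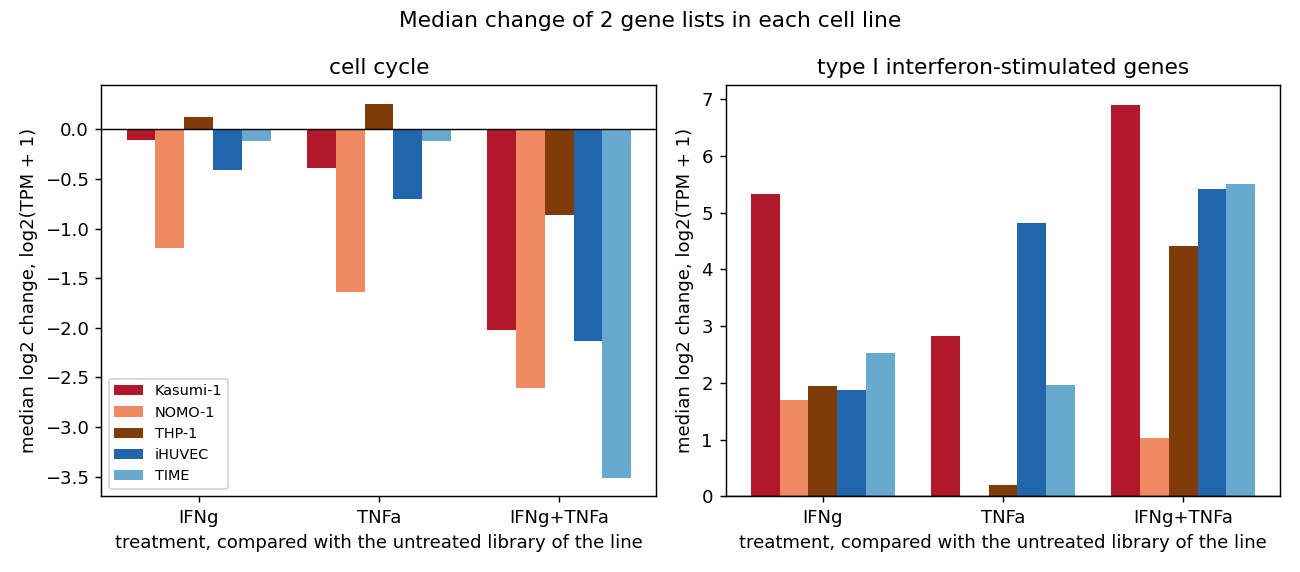
Median log2 change on log2(TPM + 1) over the cell cycle list and the type I interferon-stimulated list in each of the 5 lines, by treatment. Each bar compares 1 treated library with the untreated library of its line. With both cytokines the cell cycle median lay between -3.51 in TIME and -0.86 in THP-1, and after TNFa the type I list had a median of 4.82 in iHUVEC, 2.83 in Kasumi-1 and 1.96 in TIME.

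In endothelial lines both cytokines raised CXCL10 by 12.87 ± 1.76 (adjusted p = 6.2e-04), CXCL9 by 12.26 ± 1.05 (adjusted p = 2.4e-05), IDO1 by 10.60 ± 1.11 (adjusted p = 1.1e-04) and CX3CL1 by 9.44 ± 0.63 (adjusted p = 4.1e-06). APLN, which encodes the vascular peptide apelin, fell by 5.43 ± 0.71 (adjusted p = 4.6e-04), RGS4, a regulator of G protein signals, by 4.33 ± 0.56 (adjusted p = 3.9e-04), and LYVE1 by 3.54 ± 0.23 (adjusted p = 3.2e-06). IL3RA rose by 3.72 ± 0.47 (adjusted p = 3.7e-04), from 1.82 ± 1.23 to 36.4 ± 17.8 TPM (SD), and CD38 rose by 5.44 ± 0.83 (adjusted p = 0.001), from 0.0286 ± 0.0115 to 53.9 ± 45.2 TPM. CD93 (-1.07 ± 0.46, adjusted p = 0.135), PECAM1 (-1.16 ± 0.41, adjusted p = 0.079) and CDH5 (-0.61 ± 0.20, adjusted p = 0.057) did not pass.

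Chemokines rose in 17 of 23 cases in endothelial lines after both cytokines, also adjusted over the list alone (camera adjusted p = 9.7e-24), and cytokines in 13 of 22 and 15 adjusted over the list alone (camera adjusted p = 2.0e-13), including TNFSF10 (6.98 ± 1.43) and TNFSF13B (6.86 ± 0.81). IFNg core genes rose in 36 of 42 cases and 39 adjusted over the list alone, including GBP5 (8.87 ± 0.95), with a camera adjusted p of 6.8e-42, and 0.095 with an estimated correlation. MHC class I presentation genes rose in 16 of 21 cases and 19 adjusted over the list alone, including TAP1 (5.81 ± 0.75), in the MHC window, with a camera adjusted p of 2.1e-23, and 0.064 with an estimated correlation. Type I interferon-stimulated genes rose in 32 of 34 cases and 33 adjusted over the list alone, including the antiviral genes MX1 (8.35 ± 1.42) and RSAD2 (7.76 ± 1.62), with a camera adjusted p of 8.9e-32, and 0.155 with an estimated correlation. NF-kB genes rose in 20 of 29 cases and 23 adjusted over the list alone, including BIRC3 (7.09 ± 0.68), with a camera adjusted p of 2.6e-25, and 0.151 with an estimated correlation. Of 17 leukocyte adhesion genes 3 rose, ICAM1 (6.86 ± 0.52), VCAM1 (5.12 ± 1.21) and SELE (3.56 ± 0.42), and 1 fell, also adjusted over the list alone. The list had a camera adjusted p of 0.023, and 0.535 with an estimated correlation.

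Endothelial markers fell in 12 of 35 cases after both cytokines and 1 rose, and 16 fell and 1 rose adjusted over the list alone, with SOX18 (-3.64 ± 0.38), EMCN (-3.56 ± 0.33) and NOS3 (-2.41 ± 0.32) among those that fell. For these genes the camera adjusted p was 8.2e-04, and 0.064 with an estimated correlation. Cell cycle genes fell in 28 of 30 cases and 30 adjusted over the list alone, including TOP2A (-3.60 ± 0.52), CDC20 (-3.47 ± 0.54) and the mitotic kinase PLK1 (-3.42 ± 0.52), with a camera adjusted p of 9.7e-17, and 0.281 with an estimated correlation. In vasoregulation and coagulation 5 of 17 genes rose, including PTGS2 (5.62 ± 0.80) and tissue factor, F3 (3.31 ± 0.95), and 3 fell, including thrombomodulin, THBD (-2.35 ± 0.52), and 6 and 3 adjusted over the list alone. The camera adjusted p of that list was 0.073.

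With both cytokines 2178 genes changed in endothelial lines, 629 higher and 1549 lower. The count was 117 with no replicate block, 4686 with endothelial libraries alone, 1391 with a pseudocount of 0.1, 967 without iHUVEC and 514 without TIME, and under median-of-ratios scaling 1005 were higher and 673 lower. Of the 40 named and called genes 23 kept their call without any 1 line, and those that did not include CD38 without TIME and F3 without NOMO-1, THP-1 or TIME. With iHUVEC or TIME left out, the spread came from AML lines alone, so a kept call says little for genes near 0 there. Across cell types 282 genes rose in both and 688 fell in both, by calls that share 1 spread per gene.

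**Figure D4:**
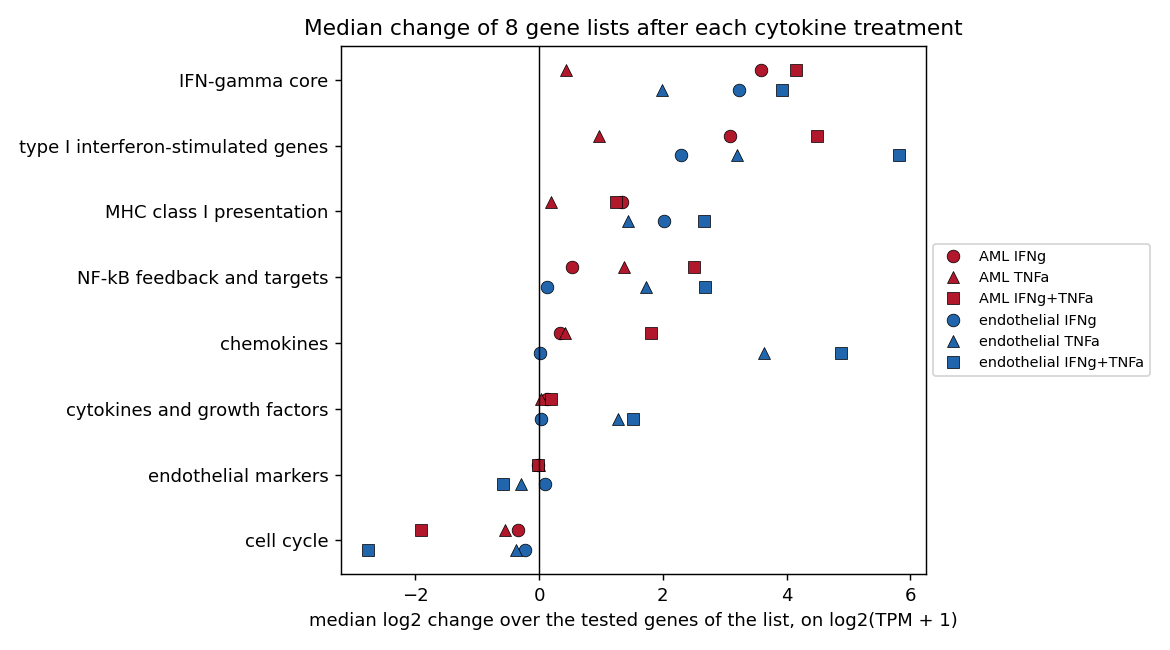
Median log2 change on log2(TPM + 1) over the tested genes of 8 gene lists, with AML lines in red, endothelial lines in blue and the treatments as circles, triangles and squares. Cell cycle medians with both cytokines were -1.91 in AML lines and -2.77 in endothelial lines, and chemokine medians were 1.81 and 4.88.

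The difference between the AML and endothelial responses was tested directly. For both cytokines CX3CL1 had the more negative response in AML lines (-9.42 ± 0.81, adjusted p = 9.3e-05), as did the complement genes C1S (-6.84 ± 1.13, adjusted p = 0.007) and C1R (-6.44 ± 0.79, adjusted p = 0.001), the phospholipase PLA1A (-6.80 ± 0.91) and CD74 (-5.07 ± 0.85, adjusted p = 0.008). CX3CL1 and PLA1A stayed below 1 TPM in every AML library, so their differences are those of the endothelial rise. CD74 rose in both cell types. It went from 164 to 3950 TPM in Kasumi-1, 101 to 227 in NOMO-1 and 49.5 to 1210 in THP-1. In endothelial lines it went from 0 to 372 in iHUVEC and 0.898 to 680 in TIME. The untreated level of CD74 was thus lower in endothelial lines, and among AML lines its rise was smallest in NOMO-1. What part each has in the difference was not tested. The chemokine CCL4 (6.58 ± 0.80, adjusted p = 0.001), IL1RN (5.16 ± 1.19, adjusted p = 0.041) and SLAMF7 (5.20 ± 1.12, adjusted p = 0.028) had the more positive response in AML lines. C1S, CD74, IL1RN and SLAMF7 lost their calls without at least 1 line. Endothelial markers had the more positive response in AML lines in 5 of 35 cases and 10 adjusted over the list alone (camera adjusted p = 8.3e-05). Among them were EMCN (3.56 ± 0.42) and LYVE1 (3.54 ± 0.29), which were near 0 in AML lines throughout. The median change of the list was -0.01 in AML lines and -0.58 in endothelial lines, so its difference is mainly the endothelial fall. The difference for IL3RA did not pass (-2.45 ± 0.61, adjusted p = 0.058).

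With TNFa CXCL5 (-4.35 ± 0.23, adjusted p = 1.7e-06), MMP10 (-5.75 ± 0.54, adjusted p = 4.6e-04), CSF2 (-4.79 ± 0.35, adjusted p = 3.5e-05) and SELE (-3.91 ± 0.54, adjusted p = 0.009) had the more negative response in AML lines. These 4 genes stayed below 1 TPM in every AML library, so the differences are those of the endothelial rise. SELE lost its call without NOMO-1. FTH1 had the more positive response in AML lines (2.71 ± 0.47, adjusted p = 0.035), a call lost under median-of-ratios scaling (adjusted p = 0.066) and without Kasumi-1, THP-1, iHUVEC or TIME. Chemokines had the lower response in AML lines in 3 of 23 cases, 1 without NOMO-1, and 8 adjusted over the list alone, with a camera adjusted p of 5.1e-10, and 0.097 with an estimated correlation. With IFNg 1 gene differed, TCIM (-2.23 ± 0.23, adjusted p = 0.005), a regulator of Wnt signals listed at 0 in AML lines, which lost its call without Kasumi-1, NOMO-1 or THP-1, and IDO1 (-6.51 ± 1.43, adjusted p = 0.368) and CD74 (-4.58 ± 0.85, adjusted p = 0.278) did not pass.

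The responses differed in 343 genes for both cytokines (208 more positive in AML lines, 135 more negative), in 39 for TNFa (16 and 23) and in 1 for IFNg. With no replicate block the counts were 17, 6 and 0, with a pseudocount of 0.1 they were 171, 11 and 0, and leaving out a line gave 78 to 640, 8 to 117 and 0 to 56. For both cytokines the count was 640 without Kasumi-1, 547 without NOMO-1 and 78 without THP-1. For TNFa it was 20 under scaling, 23 with mitochondrial genes removed, 68 without a filter, 17 without Kasumi-1, 10 without NOMO-1, 8 without THP-1, 69 without iHUVEC and 117 without TIME. For IFNg it was 0 without Kasumi-1, NOMO-1 or THP-1, 56 without iHUVEC, 29 without TIME and 16 without a filter.

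The combined treatment was also compared with the sum of the log2 changes of the single treatments. In endothelial lines CSF2 lay below that sum (-3.14 ± 0.38, adjusted p = 0.015), with 29.2 ± 18.8 TPM (SD) after TNFa and 2.15 ± 0.891 after both cytokines. C6orf58 (-2.79 ± 0.38, adjusted p = 0.031) and the pseudogene ANKRD26P1 (-2.04 ± 0.25, adjusted p = 0.015), named after its value was seen, lay below as well. CCL8, a chemokine, did not pass in endothelial (8.17 ± 1.49, adjusted p = 0.282) or AML lines (5.61 ± 1.22, adjusted p = 0.939), nor did CXCL9 (5.04 ± 1.22, adjusted p = 0.939) or IDO1 (4.46 ± 1.3, adjusted p = 0.939) in AML lines.

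Among the lists, cell cycle genes lay below the sum in endothelial lines (median -2.17 log2), with 0 of 30 lower over all genes and 22 adjusted over the list alone (camera adjusted p = 1.0e-30, and 0.151 with an estimated correlation). In AML lines they lay below it as well, with 0 lower by either adjustment (camera adjusted p = 1.0e-09, and 0.499 with an estimated correlation). Chemokines lay above the sum in endothelial (median 0.30, camera adjusted p = 1.8e-08) and AML lines (0.42, 6.0e-07), with 3 of 23 higher adjusted over the list alone in each, and NF-kB genes did so too (0.18, 7.4e-04, and 0.37, 1.2e-04). The IFNg core list (-1.27, 7.3e-05) and MHC class I presentation (-1.10, 7.3e-04) lay below it in endothelial lines. No list passed with an estimated correlation, the lowest adjusted p being 0.077, for endothelial markers in endothelial lines.

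In AML lines 743 of 15043 genes had an unadjusted limma p under 0.05, no more than the share of 0.05 that arises without any departure. There limma called 0 genes, and 1 under scaling, 1 with mitochondrial genes removed, 11 without NOMO-1 and 1 without THP-1. In endothelial lines it called 3, all lower, and 0 with no replicate block, with a pseudocount of 0.1, at 5 TPM, under scaling or with endothelial libraries alone. The endothelial count was 27 without a filter, 0 without Kasumi-1, 1 without NOMO-1, 0 without THP-1, 78 without iHUVEC and 30 without TIME.

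The shares of transcripts within genes were compared between both cytokines and no treatment over the 5 lines. The share of TANK-201, a transcript of a TRAF-binding adaptor gene, rose by 52.8 ± 6.6 percentage points (adjusted p = 0.004), from 3.4 to 56.2%, in 5 of 5 lines. WARS-204, from the tryptophan tRNA synthetase gene, rose by 48.3 ± 7.8 points (adjusted p = 0.016), from 27.2 to 75.4%. In TMEM63B the share of transcript 201 rose by 54.2 ± 10.0 points (adjusted p = 0.026), in 4 of 5 lines, while that of the transcript ENST00000323267 changed by -57.2 ± 7.6 (adjusted p = 0.006). The shares of the GPN2 transcript ENST00000374135 (-42.2 ± 4.5, adjusted p = 0.002), SLC25A22-228 (-48.0 ± 9.3, adjusted p = 0.028) and CD2BP2-201 (-41.2 ± 7.5, adjusted p = 0.025) fell, lower in all 5 lines.

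Of 11949 transcripts in 4818 genes, 70 changed their share, 33 upward and 37 downward, in 62 genes. The count was 2 with no replicate block, 5 without Kasumi-1, 7 without THP-1, 20 without iHUVEC and 1 without TIME.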

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

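The differences between the responses of AML and endothelial lines were planned, and every test that weighs an explanation was chosen after the result was seen. Each result in the next 3 paragraphs is listed because the difference between the responses of the cell types passed its test, for single genes by limma at an adjusted p under 0.05 and for lists by the camera test at the preset correlation. Values are AML minus endothelial responses in log2, and for lists the median over members. A gene near 0 throughout AML lines, such as LYVE1, EMCN or TCIM, takes its difference from 2 endothelial lines, and its error is understated.

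For IFNg the responses differed in 1 gene, TCIM (-2.23), which lost its call without Kasumi-1, NOMO-1 or THP-1. The lists that differed were MHC class I presentation (median -0.14), NF-kB targets (0.40) and mitochondrial mRNAs (-0.32), and none of these 3 calls held with an estimated correlation (adjusted p = 0.624, 0.850 and 0.355).

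For TNFa the responses differed in 39 genes. Among the named ones, FTH1 (2.71), LYVE1 (2.80), EMCN (2.45) and CCL14 (2.39) were more positive in AML lines. MMP10 (-5.75), CX3CL1 (-5.08), SLC7A2 (-4.82), CSF2 (-4.79), CXCL5 (-4.35) and SELE (-3.91) were more negative. EMCN, CCL14, CX3CL1, SLC7A2 and SELE lost their calls without NOMO-1, FTH1, EMCN and CX3CL1 under median-of-ratios scaling, and LYVE1 and FTH1 without another line. The lists with lower responses in AML lines were the IFNg core list (-1.36), MHC class I presentation (-1.30), type I interferon-stimulated genes (-2.15), NF-kB targets (-0.53), chemokines (-1.87), cytokines (-1.27), T-cell ligands (-0.29) and cell death (-0.30). Endothelial markers (0.25) and epithelial markers (0.30) had higher medians. None of these list calls held with an estimated correlation, the lowest adjusted p being 0.062 for endothelial markers.

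For both cytokines the responses differed in 343 genes. The granule genes CTSG (-6.35), PRTN3 (-5.15) and RNASE2 (-3.73) fell in AML lines, and CX3CL1 (-9.42), C1S (-6.84), PLA1A (-6.80), C1R (-6.44), LGALS9 (-5.68), CD74 (-5.07), CXCL5 (-4.92), PTGS2 (-4.57), TNFSF13B (-4.40) and SELE (-3.57) also had the more negative response there. CCL4 (6.58), APLN (5.32), SLAMF7 (5.20), IL1RN (5.16), RGS4 (4.33), EMCN (3.56), LYVE1 (3.54), SOX18 (3.49) and EGR2 (2.71) had the more positive one. CD74 rose in both cell types, from a higher untreated level in AML lines. PTGS2 lost its call without NOMO-1 (adjusted p = 0.109), and APLN, SLAMF7, IL1RN, C1S, CTSG, LGALS9, CD74, SELE and EGR2 without another line. The lists that differed were MHC class I presentation (-1.02), type I interferon-stimulated genes (-0.86), chemokines (-1.93), cytokines (-1.05), endothelial markers (0.42), endothelial surface antigens (0.46) and cell cycle (0.86). Of these the call of endothelial markers held with an estimated correlation (adjusted p = 0.038). Their median change was -0.01 in AML lines and -0.58 in endothelial lines, so this difference mainly restates the endothelial fall. Under median-of-ratios scaling type I interferon-stimulated genes (median -0.68, camera adjusted p = 0.387), endothelial surface antigens (0.22, 0.447) and cell cycle (0.47, 0.094) lost their calls. Endothelial markers kept theirs with a smaller median (0.20, 0.047). The type I call was also lost without NOMO-1 (camera adjusted p = 0.968).

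Type I interferon-stimulated genes changed after TNFa by a median of 4.82 log2 in iHUVEC, 2.83 in Kasumi-1, 1.96 in TIME, 0.19 in THP-1 and 0.00 in NOMO-1, on single libraries. In iHUVEC, IFNg in the culture or a swap with the IFNg library is argued against by a median 2.46 log2 above the IFNg library over the list, with CIITA at 0.412 against 39.4 TPM. The scale of that library is argued against by a difference to TIME of 3.19 log2 after scaling. IFNB1 stood at 2.94 TPM in iHUVEC after TNFa, so type I interferon made in that culture is a candidate explanation for iHUVEC. IFNB1 was at 0.242 TPM in Kasumi-1 and 0.0887 in TIME after TNFa, too near 0 to decide on type I interferon there, and IFNg in the Kasumi-1 culture, with CIITA at 33.4 TPM after TNFa against 21.9 after IFNg, also stays open.

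Cell cycle genes fell after both cytokines in both cell types. The scale of the libraries is argued against, since the scaled median changes were at or below -1.79 log2. NOMO-1 alone is argued against, since the medians of the other 4 lines were at or below -0.86, the value of THP-1. In 39 centromere, kinetochore, condensin and GINS genes outside the list the scaled median was at or below -0.70 in every line. Their mean followed that of the list with a correlation of 0.99 over the 15 libraries without the combined treatment, so their fall restates the pattern, and whether cells divided less or another cause lowered the transcripts stays open, since cell numbers were not analysed here.

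With 6 AML libraries there are 10 splits into 3 and 3, too few for a share under 0.05. The real split was the 1 split with as many genes in each case, with 97 genes for IFNg and at most 1 in the others, 13 for TNFa and at most 2, and 3907 for both cytokines and at most 0. Of the 10 splits 4 part the libraries of every line, the real one among them, and the other ones of these gave at most 0 genes.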

How the results depend on the processing

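The removal of mitochondrial genes, and the gene list calls without a line or without MHC genes, were added after the data were seen, and the other alternatives were planned. Counts are of genes at an adjusted p under 0.05 unless stated, counts not given stayed within 1.5 times their value, and the cause of each shift was not tested except where fewer libraries or genes explain it.

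With no replicate block, AML counts were 7 for IFNg (97 before), 0 for TNFa (13) and 66 for both cytokines (3907), and endothelial counts 11 (64), 16 (154) and 117 (2178). Response differences were 0 for IFNg (1), 6 for TNFa (39) and 17 for both cytokines (343), the endothelial departure from additivity 0 (3), and transcript shares 2 (70). The treatment counts therefore rest on pairing libraries by line.

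With a pseudocount of 0.1 the counts were 32 for AML TNFa, 81 for endothelial TNFa, 1391 for endothelial lines with both cytokines, 0, 11 and 171 for the response differences to IFNg, TNFa and both, and 0 for endothelial additivity. Without a filter on low values they were 480 for untreated AML against endothelial lines (1099), 0 for the same with both cytokines (860), 49 for AML IFNg, 105 for endothelial IFNg, 16 and 68 for the response differences to IFNg and TNFa, and 27 for endothelial additivity. At 5 TPM AML TNFa gave 22 and endothelial additivity 0. Without the variance trend AML against endothelial lines with both cytokines gave 368.

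Under median-of-ratios scaling the counts were 187 for AML IFNg, 55 for AML TNFa, 20 for the response difference to TNFa, 1 for AML additivity (0) and 0 for endothelial additivity. With mitochondrial genes removed they were 153, 57, 23 and 1 for the first 4 of these. With the libraries of the cell type alone they were 3 for AML TNFa, 2474 for AML lines with both cytokines, 36 for endothelial IFNg, 4686 for endothelial lines with both and 0 for endothelial additivity.

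Leaving out each line in turn gave 105 to 1711 for AML against endothelial lines untreated and 0 to 1687 with both cytokines. AML counts ran from 25 to 85 for IFNg, 0 to 43 for TNFa and 2052 to 3245 for both, and endothelial counts from 22 to 117, 55 to 206 and 514 to 2962. Response differences ran from 0 to 56 for IFNg, 8 to 117 for TNFa and 78 to 640 for both. Additivity counts ran from 0 to 11 in AML and 0 to 78 in endothelial lines, transcript shares from 1 to 96 and gene list calls from 127 to 139 (136). Where 1 endothelial library was left, it was assumed to vary like the other groups. For a gene near 0 in AML lines a kept call then says little.

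Gene list calls numbered 11 with an estimated correlation and 53 by fry. In all, 91 of these counts moved and 93 did not. Over the named genes and alternatives, 2762 results kept their direction and side of the threshold, 593 lost their call, 30 gained one and 0 reversed. Depth is unknown for TPM, so no limit from depth was computed.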

Other observations

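CDKN1A, IFNB1, IFNL1 and HLA-DRB1 were chosen after their values were seen, and so were the values of the other genes in this part and the tests of the HLA genes. CDKN1A, which encodes the cell cycle inhibitor p21, rose in AML lines after both cytokines (6.15 ± 0.74, adjusted p = 3.3e-04), from 0.429 to 505 TPM in Kasumi-1, from 1.09 to 50.8 in NOMO-1 and from 7.33 to 336 in THP-1. GFI1, a repressor that guides granulocyte differentiation, went from 118 to 20.3, from 9.49 to 0.0851 and from 109 to 18 TPM in the same lines. GHRL stood at 47.4, 44.0 and 12.8 TPM after TNFa in Kasumi-1, NOMO-1 and THP-1 and at 2.43, 9.49 and 1.27 TPM after both cytokines.

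Kasumi-1 had the only IFNL1 value above 1 TPM, 30.1 after both cytokines, beside IFNB1 at 31.1, and IFNB1 reached 9.46 TPM in iHUVEC after both. RUNX1T1, the partner of the fusion that Kasumi-1 carries, stood at 38.4 TPM in untreated Kasumi-1 and at 0 in untreated NOMO-1 and THP-1. EPCAM, an epithelial marker, went from 107 to 14.7 TPM in Kasumi-1 after both cytokines.

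HLA-DRA was listed at 0 in 19 libraries and at 0.0400 TPM in untreated TIME, although CD74 reached 3950 TPM in Kasumi-1 after both cytokines. Class II genes silent in every line are argued against by HLA-DRB1, which reached 289 TPM in THP-1. The part of the TPM outside the gene table was larger after IFNg than untreated in 5 of 5 lines, so reads assigned to features outside the table may account for the low HLA values. Other genes induced by IFNg outside the table would give the same sign.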
